A study of Mus musculus with 30 samples.

How the data were processed

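The samples come from 3 mouse oral squamous carcinoma models, MOC1, MOC1E1 (called MOC1esc1 in part of the labels) and MOC22, grown in C57BL/6J mice. Single-cell libraries cover isotype, anti-PD-1 and anti-CTLA-4 treatment for MOC1 and MOC1E1, and isotype and anti-PD-1 treatment for MOC22. That makes 8 single-cell RNA libraries and 8 matching T cell receptor libraries, 1 per group. Bulk RNA covers untreated MOC1 and MOC1E1 tumours and cultured MOC1 and MOC1E1 cells in 4 groups of 3 libraries. The labels call the MOC1 RNA material and the MOC22 material T cells, and the MOC1 receptor material and the MOC1E1 material immune cells. The 2 exome samples were not analysed here.

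Per the labels, single-cell libraries were made with the 10x 5' gene expression kit and its V(D)J receptor kit, and bulk RNA was extracted with RNeasy columns and prepared with an Illumina mRNA kit. The deposited single-cell matrices hold whole UMI counts per gene and barcode, as whole numbers in the deposited files show. The deposited bulk tables hold TPM, and each of the 12 columns sums to the fixed TPM total apart from rounding, so sequencing depth cannot be read from them. The submitters' processing notes name Cell Ranger 3.0.2, Seurat without a version, Trimmomatic 0.36, kallisto 0.46.0 and DESeq2. The same notes list both the human build GRCh38 and the mouse build mm10, and the sources used here do not give the role of either; all gene symbols in the tables are mouse symbols. The deposited receptor tables give contigs with V and J genes, CDR3 sequences and UMI counts.

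The descriptions of the MOC22 receptor samples each name the table of the other; the treatment in the table name was used, and 97.3% and 96.2% of anti-PD-1 and isotype receptor barcodes lay in the RNA library of the same treatment. Some receptor tables are named MOC1 but belong to MOC1E1 by their labels, and 81.6 to 88.5% of barcodes lay in the matching MOC1E1 RNA library and at most 0.91% in any other library. Culture columns carry names containing "plusifng" and MOC1 replicate numbers 4 to 6 and MOC1E1 numbers 10 to 12, while the labels give no treatment. Whether the 3 libraries of a bulk group come from separate mice or separate culture passages is not given in the sources used here. The p-values therefore measure only the spread between these samples.

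The comparisons, gene lists, limits and alternatives were fixed before the data were examined, except where the text says that a choice was made after seeing the data. A count test had been planned for bulk RNA; since the tables hold TPM, the planned fallback was used. Genes with TPM of at least 1 in 3 libraries of a comparison were kept, and log2(TPM + 1) values were fitted with limma-trend (limma 3.58.1, R 4.3.3, and data.table in version 1.17.8). Moderated p-values were adjusted with Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p of 0.05 or less. Fold changes are on this log2(TPM + 1) scale, MOC1E1 minus MOC1, and shrink for genes of low TPM. The interaction, over all 12 libraries, is the tumour difference minus the culture difference. Gene lists with at least 5 tested members were tested with limma camera at a fixed correlation of 0.01 and adjusted over the lists, then again with an estimated correlation. Member p-values were also adjusted over the list alone. Where a list name below reads as a cell type, it names marker genes in whole-tumour RNA and not counted cells. The genes named are the 8 largest rises and 8 largest falls among called genes with a mean TPM of at least 8 over the 6 libraries and no overlap between groups, plus the 3 members with the smallest p of each list that was called or had at least 3 called members. For the interaction the 8 genes with the smallest p are named. Socs3 in cultures, Vim in tumours and Ifit3 in tumours were named after their values were seen.

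Single cells were kept with at least 300 genes and at most 10% mitochondrial UMIs. The MOC1 matrices hold cells without a mitochondrial limit, while the MOC1E1 and MOC22 matrices hold none above 5%. Hashtag features were split from genes in the MOC1 matrices and assigned with a threshold per tag. Doublet scores came from scrublet as run in scanpy 1.11.5 with an expected rate of 0.06. Its automatic threshold marked 0 to 5 cells per library, so the highest scores were removed instead at 0.8% per 1000 cells, a rule set after seeing the data. It removed 23 of 174, 14 of 153 and 18 of 124 cells with more than 1 hashtag in the MOC1 isotype, anti-PD-1 and anti-CTLA-4 libraries, so most such doublets stayed in. Each model was clustered on its own libraries together: 10000 counts per cell, log scale, 2000 variable genes, 30 components, 15 neighbours, leiden resolution 1, seed 0, with no batch correction (anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, Python 3.11.15). Clusters were named from fixed markers. A T cell cluster is CD8 T-like when at least 60% of its cells hold Cd8a or Cd8b1 and at most 25% hold Cd4, CD4 T-like when at least 50% hold Cd4 and at most 25% hold Cd8a, and Treg-like when at least 40% hold Foxp3 and Cd4 is the commoner coreceptor. The Treg-like limit was 50% at first and was lowered after the MOC22 clusters were seen. A cluster whose 10 leading genes hold more markers of another type than of its own keeps no class name. Clusters that meet no rule are called other T or unnamed.

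Each single-cell comparison has 1 library per group. There is no replicate check for them, so no test, p-value or count of changed genes is given. Class shares carry exact 95% intervals and expression ratios carry exact conditional intervals from summed UMIs; both cover counting error only. Expression is given as CPM, the UMIs of a gene scaled to the total of its class sum, and ratios as log2 of CPM + 10. List medians were placed among 10000 random lists matched on expression. The genes named per class are the 5 highest and 5 lowest ratios among genes with at least 50 UMIs and an interval that excludes 1, without receptor, mitochondrial, ribosomal and unnamed genes, plus a fixed panel. A clone is a set of cells of 1 library with the same nucleotide CDR3 sequences of both receptor chains. Clone shares were compared after thinning all libraries of a model to the same number of paired cells over 100 draws. In a self-test with 200 genes changed by a known amount, intervals held the true ratio in 94.6 to 95.6% of cases. A bulk self-test with 200 changed genes found 63.0% of genes changed by 1 log2 unit and 93.0% of those changed by 2 in tumours, and 88.0% and 99.0% in cultures. Among called genes, 9 of 165 in tumours and 14 of 201 in cultures were not among the changed genes.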

Results

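RNA and T cell receptors were measured in single cells from tumours of 3 mouse oral squamous carcinoma models. PD-1 and CTLA-4 are inhibitory receptors of T cells, and antibodies that block them are used as checkpoint therapy. Mice with MOC1 or MOC1E1 tumours had received an isotype control antibody, anti-PD-1 or anti-CTLA-4, and mice with MOC22 tumours an isotype control or anti-PD-1, injected on days 3, 6 and 9. The series text asks how T cells in tumours differ between responding and resistant conditions. Each of the 8 conditions has 1 RNA library and 1 receptor library. MOC1 RNA libraries held 28466596 UMIs over 4943 barcodes with isotype, 24040712 over 3890 with anti-PD-1 and 24728203 over 3876 with anti-CTLA-4. MOC1E1 libraries held 17309104 UMIs over 3473 barcodes, 26937406 over 4928 and 14766019 over 3127 in the same order. MOC22 libraries held 18596562 UMIs over 2776 barcodes with isotype and 18200479 over 2755 with anti-PD-1. After filtering, 4508, 3566 and 3576 MOC1 cells, 3374, 4724 and 3038 MOC1E1 cells and 2712 and 2694 MOC22 cells remained. Bulk RNA was measured in untreated MOC1 and MOC1E1 tumours and in cultured cells of both lines, 3 libraries per group. The bulk tables give TPM without counts, so their depth is unknown.

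In MOC1 tumours, CD8 T-like cells, the class of cytotoxic T cells, made up 10.999% of T cells with isotype (exact 95% interval 10.1 to 11.98%). Their share was 30.8% (29.2 to 32.3%) with anti-PD-1 and 56.3% (54.6 to 58.0%) with anti-CTLA-4. Treg-like cells, whose marker Foxp3 encodes the lineage factor of regulatory T cells, went the other way: 39.9% (38.5 to 41.4%) with isotype, 21.3% (19.9 to 22.7%) with anti-PD-1 and 2.96% (2.42 to 3.58%) with anti-CTLA-4. There were thus 0.275 CD8 T-like cells per Treg-like cell with isotype, 1.45 with anti-PD-1 and 19.1 with anti-CTLA-4. CD4 T-like cells made up 16.6, 19.0 and 24.8% of T cells, and gamma-delta T-like cells 6.73, 2.02 and 0.927%. Each MOC1 library carries 4 hashtags, antibody barcodes whose meaning the labels do not give. Across the hashtags, CD8 T-like shares ran from 7.59 to 12.6% with isotype, 18.9 to 38.5% with anti-PD-1 and 47.4 to 62.9% with anti-CTLA-4, without overlap. Treg-like shares ran from 35.9 to 46.7%, 15.8 to 32.2% and 1.70 to 3.93%. With cells thinned to 2000 UMIs and classed by single transcripts, the Treg-like differences from isotype were -11.7 and -22.8 percentage points, against -18.7 and -37.0 by cluster.

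**Figure D1:**
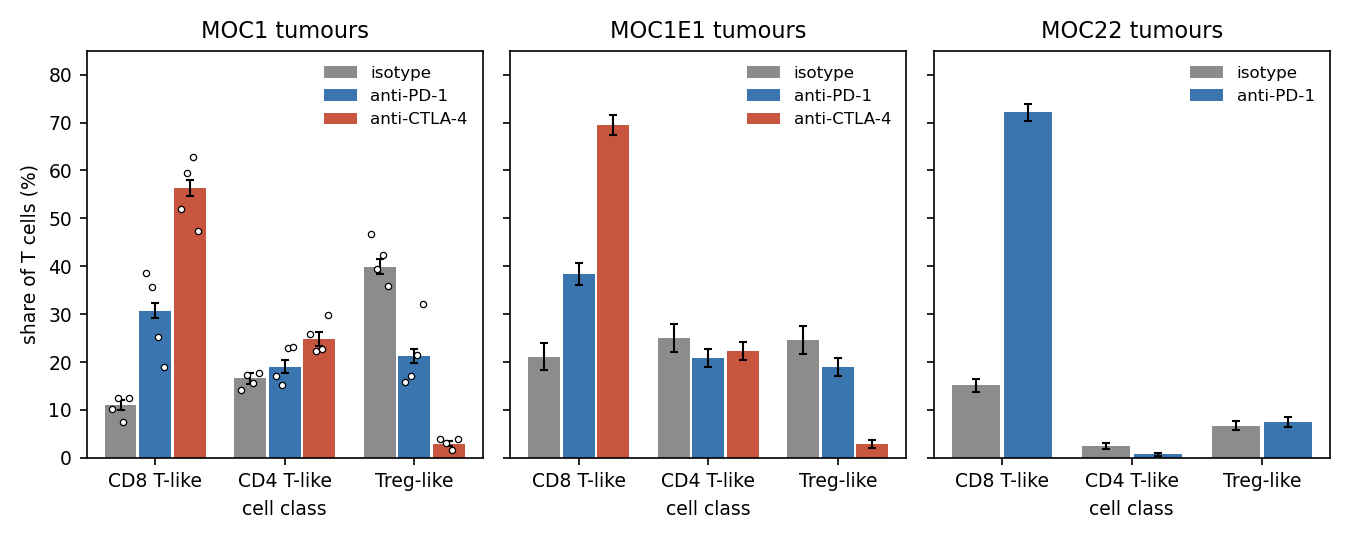
Bars give the share of T cells (%) in the CD8 T-like, CD4 T-like and Treg-like classes by model and treatment, with exact 95% intervals of counting error, and white points are the MOC1 hashtags. CD8 T-like bars stand higher with treatment in each model, and Treg-like bars are near 3% with anti-CTLA-4 (2.96% in MOC1 and 2.80% in MOC1E1).

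In CD8 T-like cells of MOC1 tumours, anti-PD-1 went with more transcripts of cytotoxic and inhibitory receptor genes and fewer of memory genes. Prf1, which encodes the pore-forming protein perforin, stood at 417 CPM (404 to 431) against 72.1 (62.3 to 83.0) with isotype. Gzmb, the protease granzyme B, stood at 1444 against 405 CPM, and the inhibitory receptor gene Lag3 at 941 against 176 CPM. Pdcd1, the gene of PD-1 itself, stood at 1027 against 439 CPM, Havcr2 (TIM-3) at 117 against 33.8 CPM, and Tox, a transcription factor of exhausted T cells, at 158 against 66.9 CPM. Of 20 measured exhaustion and checkpoint receptor genes 17 were higher (median log2 ratio 0.98), as were 19 of 24 effector and cytotoxic genes (median 0.52) and 13 of 13 glycolysis genes (median 0.76). Each of these medians lay above all 10000 random lists of like expression. Of 19 memory and progenitor genes 18 were lower (median -0.79, below all random lists), among them Tcf7 (22.3 against 91.5 CPM), Klf2 (107 against 368 CPM) and Il7r, the interleukin 7 receptor (74.2 against 222 CPM). The type I interferon list had a median of -0.24, with 18 of 27 genes lower. The other lists ran from -0.24 for dissociation and stress through 0.13 for T helper 1 genes, 0.14 for tissue residency and 0.27 for cell cycle genes to 0.29 for the regulatory T cell programme. Different clusters held most CD8 T-like cells: cluster 5 with isotype (370 of 469), cluster 6 with anti-PD-1 (587 of 1065) and cluster 1 with anti-CTLA-4 (1532 of 1944). A cluster mostly of 1 library may be that library and not a cell type.

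Anti-CTLA-4 in MOC1 tumours went with another CD8 T-like profile. Il12rb2, a chain of the interleukin 12 receptor, stood at 101 CPM (95.9 to 106) against 14.1 (10.0 to 19.4) with isotype, and Ifng, the gene of interferon gamma, at 221 against 100.4 CPM. Csf1, a macrophage growth factor, stood at 59.2 against 7.4 CPM, and Cd74, the invariant chain of MHC class II, at 126 against 18.2 CPM. Gzmb was higher (686 against 405 CPM), while Gzma (97.9 against 469.9 CPM) and Prf1 (47.7 against 72.1 CPM) were lower. Tox stood at 17.5 against 66.9 CPM and Lag3 at 159.5 against 176 CPM, unlike the anti-PD-1 library. Bcl2, a survival gene, stood at 14.7 against 146 CPM, Klf2 at 67.2 against 368 CPM and Klf3 at 3.1 against 106 CPM. The T helper 1 list had a median of 0.50 (8 of 12 higher), glycolysis 0.42 (12 of 13 higher), exhaustion 0.26 (12 of 20 higher) and cell cycle 0.18 (24 of 27 higher). The memory list had a median of -0.69 (13 of 19 lower) and the type I interferon list -0.44 (25 of 27 lower). Effector and cytotoxic genes split evenly, 12 higher and 12 lower, with a median of 0.06 that lay above 49.6% of random lists; with cells classed by transcripts it was 0.41. Tissue residency, the regulatory T cell programme and stress genes had medians of -0.01, -0.05 and -0.085.

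Treg-like cells of MOC1 tumours also differed by treatment. With anti-PD-1 the chemokine gene Ccl4 stood at 630.3 against 199 CPM, Lag3 at 741 against 296 CPM, and the killer cell lectin receptor gene Klrc1 at 78.1 against 24.9 CPM. Effector and cytotoxic genes had a median log2 ratio of 0.39 (18 of 22 higher) and cell cycle genes -0.245, with 26 of 27 lower. Cd8b1, a gene of CD8 T cells, stood at 228 against 134 CPM in the same cells, and RNA from CD8 T cells was not separated from their own. Il9, the gene of interleukin 9, gave 888 UMIs (72.2 CPM) with isotype and 0 with anti-PD-1 (upper bound 0.8 CPM) and with anti-CTLA-4 (upper bound 3.7 CPM). All tagged Il9 transcripts carried 1 of the 4 hashtags (279 CPM, and 0 in the other 3). Of the Treg-like cells, 217 of 1703 with isotype, 59 of 736 with anti-PD-1 and 24 of 102 with anti-CTLA-4 lay in cluster 11, where 93.7% of cells held the proliferation gene Mki67, and the others in cluster 0. With anti-CTLA-4, 102 Treg-like cells remained, in which 27 of 27 cell cycle genes were higher (median 0.71), 28 of 28 type I interferon genes were lower (median -0.65) and 16 of 18 genes of the regulatory T cell programme were lower (median -0.51). Cd8a stood at 247 against 76.6 CPM and Cd8b1 at 293 against 134 CPM in the same cells, transcripts that belong to CD8 T cells.

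The MOC1E1 libraries are labelled immune cells, and T cells made up 26.5% of cells with isotype (24.99 to 28.0%), 36.1% (34.7 to 37.5%) with anti-PD-1 and 64.6% (62.9 to 66.3%) with anti-CTLA-4. CD8 T-like cells were 21.1% of T cells (18.4 to 23.9%), 38.3% (36.0 to 40.7%) and 69.5% (67.4 to 71.5%). Treg-like cells were 24.5% (21.7 to 27.5%), 18.9% (17.1 to 20.9%) and 2.80% (2.12 to 3.63%), and CD4 T-like cells 24.97, 20.8 and 22.2%. Among all cells, macrophage and monocyte-like cells were 27.8, 30.3 and 12.2%, neutrophil-like cells 20.6, 11.6 and 8.39%, and NK-like cells 15.9, 14.5 and 4.28%. An unnamed cluster, in which 58.2% of cells held the NK receptor gene Ncr1, made up 0.77% with isotype, 0.47% with anti-PD-1 and 8.20% with anti-CTLA-4. By single transcripts in cells at full depth, the CD8 differences were 10.8 and 38.8 points, against 17.2 and 48.4 by cluster; in thinned cells the Treg-like difference with anti-CTLA-4 was -11.6, against -21.7.

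In MOC1E1 CD8 T-like cells, anti-PD-1 went with higher Prf1 (271 against 52.6 CPM), Gzmb (957 against 418 CPM), Tox (142 against 54.0 CPM) and Cxcr6, a chemokine receptor of tissue T cells (594 against 234 CPM). The cytokine genes Csf2 (5.5 against 51.9 CPM), Il2 (7.3 against 45.0 CPM), Xcl1 (545 against 1770.3 CPM) and Ccl1 (258 against 1301 CPM) were lower. Effector genes had a median log2 ratio of 0.56 (16 of 23 higher), exhaustion genes 0.485 (17 of 20 higher) and memory genes -0.12 (12 of 18 lower), the last becoming -0.52 with classes read from transcripts. The 3 chains of complement C1q, which macrophages express, were among the highest ratios (C1qb 58.7 against 2.8 CPM) in libraries with 30.3 and 27.8% macrophage-like cells. With anti-CTLA-4, Gzmc stood at 82.8 against 5.5 CPM, Gzmb at 886 against 418 CPM and Cxcr6 at 675 against 234 CPM. Ccr7, a chemokine receptor gene of lymph node homing, was lower (6.0 against 58.9 CPM), as was Xcl1 (212 against 1770.3 CPM). Tissue residency genes had a median of 0.525 (8 of 11 higher), effector genes 0.42 (16 of 24 higher) and exhaustion genes 0.05 (12 of 20 higher). Medians were -0.69 for memory genes, -0.35 for type I interferon genes, -0.30 for cell cycle genes and -0.81 for the regulatory T cell programme, whose own cells were 2.80 against 24.5% of T cells. The lowest ratio was that of Lyz2, a lysozyme gene of macrophages (6.0 against 140 CPM, log2 -3.23, and -0.23 with classes read from transcripts), with macrophage-like cells at 12.2 against 27.8%. The unnamed cluster led by Gzmc stood at 8.20 against 0.77% of cells. RNA from such cells, Gzmc included, was not separated from that of CD8 T-like cells. Cluster 8 held 91 of 188 CD8 T-like cells with isotype, clusters 1 and 8 held 292 and 257 of 653 with anti-PD-1, and cluster 1 held 935 of 1364 with anti-CTLA-4. Cluster 11 of the same class held 46, 104 and 207 cells in this order. In it 80.7% of cells held Mki67, 17.1% Foxp3 and 17.9% Cd4, and the cell cycle and regulatory T cell medians include it.

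MOC1E1 Treg-like cells numbered 219 with isotype, 323 with anti-PD-1 and 55 with anti-CTLA-4. With anti-PD-1 the highest ratio was that of Jchain, a gene of plasma cells (191 UMIs, 124 CPM, against 0 UMIs, upper bound 3.9 CPM). Its log2 ratio was 0 with doublets kept or under the stricter filter. Ccl3 stood at 161 against 31.3 CPM, Gzma at 181 against 42.8 CPM and Prf1 at 51.2 against 7.3 CPM, and effector genes had a median log2 ratio of 0.51 (16 of 22 higher). Cd8b1 stood at 204 against 76.2 CPM in these cells, and RNA of other cells was not separated from their own. Ctla2a (152 against 355 CPM) and the protease gene Furin (46.0 against 113 CPM) were lower. With anti-CTLA-4, the interferon-induced gene Ifitm1 stood at 1165 against 32.4 CPM and the chemokine gene Ccl5 at 2554 against 731 CPM. The type I interferon list went the other way from Ifitm1, with 15 of 23 genes lower and 8 higher (median log2 ratio -0.31). Cd8a (465 against 65.8 CPM) and Cd8b1 (494 against 76.2 CPM) were higher in these 55 cells too.

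In MOC22 tumours, CD8 T-like cells made up 15.2% of cells with isotype (13.8 to 16.6%) and 72.1% (70.4 to 73.8%) with anti-PD-1. This difference of 57.0 points rests on how clusters were named. Cluster 0, in which 91.7% of cells held Cd8a and 0.628% Cd4, kept no class name because a marker of dendritic cells, Ccr7, which resting T cells also express, was among its leading genes. It held 29.2% of isotype cells and 0.186% of anti-PD-1 cells. Classed by their own transcripts, CD8 T cells were 28.0 points more frequent with anti-PD-1, and 5 of the alternatives gave 26.2 to 30.6 points. Cluster 2, in which 58.7% of cells held Cd4, was kept out of the CD4 class in the same way and went from 25.8% to 0.557%. Treg-like cells were 6.71% (5.80 to 7.72%) with isotype and 7.42% (6.46 to 8.48%) with anti-PD-1, a difference of 0.713 points whose interval (-0.68 to 2.11) includes 0, and which was negative under 6 alternatives (-2.62 to -1.42 points).

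In MOC22 CD8 T-like cells, without cluster 0, anti-PD-1 went with higher granzyme transcripts: Gzmf 116 against 14.7 CPM, Gzmk 396 against 82.5 CPM and Gzmb 1989 against 542 CPM. Prf1 stood at 712 against 216 CPM, Lag3 at 982.5 against 515 CPM and Ccl5 at 18729 against 5460 CPM. Lower were the chemokine genes Xcl1 (189 against 1852 CPM) and Ccl1 (215 against 1790 CPM), the integrin gene Itgae (113 against 432 CPM) and Id3, a regulator of memory T cells (3.5 against 55.6 CPM). Effector genes had a median log2 ratio of 0.31 (18 of 24 higher), glycolysis genes 0.47 (12 of 13 higher) and exhaustion genes 0.215 (11 of 20 higher). The memory list had a median of -0.45 (15 of 19 lower) and the type I interferon list -0.20 (20 of 27 lower). Under the stricter cell filter the effector and memory medians were 0.08 and -0.175. Clusters 1 and 10 held 190 and 122 of 411 CD8 T-like cells with isotype, and clusters 1 and 3 held 601 and 593 of 1943 with anti-PD-1. In 182 and 200 Treg-like cells, 19 of 22 effector genes (median 1.07) and 10 of 11 T helper 1 genes (median 1.00) were higher with anti-PD-1, among them Ccl3 (221 against 12.2 CPM) and Ccl4 (787 against 141 CPM). CD8 T-like cells, 72.1 against 15.2% of cells, hold effector transcripts too, and RNA from them was not separated: Treg-like cells held Cd8b1 at 129 against 111 CPM and Prf1 at 44.3 against 8.5 CPM, and CD8 T-like cells Cd8b1 at 1704 against 1787 CPM. The difference in effector and T helper 1 genes is thus not read as expression by Treg-like cells. Id3 (21.2 against 111 CPM) and Gpr83 (0 UMIs against 47.9 CPM) were lower there.

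Receptor libraries held 3104, 2704 and 2830 cells with both receptor chains in MOC1, 476, 896 and 750 in MOC1E1, and 1378 and 1635 in MOC22. They were 78.5, 84.9 and 85.2% of cells with a productive chain in MOC1, 48.2, 51.55 and 41.4% in MOC1E1, and 55.9 and 67.7% in MOC22. In MOC1, 535 of 3954, 349 of 3186 and 525 of 3321 cells held 2 beta chains, a sign of doublets. The counts were 38 of 987, 90 of 1738 and 55 of 1812 in MOC1E1, and 112 of 2465 and 56 of 2416 in MOC22. Cells in clones of 2 or more made up 23.2% of MOC1 cells with isotype (exact 95% interval 21.8 to 24.8%), 37.0% (35.2 to 38.9%) with anti-PD-1 and 53.5% (51.6 to 55.3%) with anti-CTLA-4. Counted within each hashtag, they ran from 16.9 to 29.0%, 30.1 to 45.8% and 38.9 to 62.4%, so those of both treatments overlap. This count splits clones that lie in several hashtags. With anti-CTLA-4, 179 of 294 clones lay in 1 hashtag, against 191 of 196 with anti-PD-1 and 212 of 215 with isotype. The overlap may thus stem in part from the counting. Over whole libraries the shares were 9.24% (6.80 to 12.2%), 29.4% (26.4 to 32.5%) and 55.3% (51.7 to 58.9%) in MOC1E1, and 23.1% (20.9 to 25.5%) and 73.6% (71.4 to 75.7%) in MOC22. At equal cell numbers, the differences from isotype were 15.2 points (12.8 to 17.5) and 31.1 (28.7 to 33.5) in MOC1, 15.2 (11.02 to 19.2) and 40.5 (35.8 to 44.8) in MOC1E1, and 49.0 (45.7 to 52.0) in MOC22. Intervals of these shares and differences count cells of 1 clone as independent, so they may be too narrow. By the deposited clonotype numbers, thinned MOC1E1 shares were 19.6% with anti-PD-1 against 9.93%. With anti-CTLA-4 they were 27.8 against 1.89% for clones of at least 5 cells, and 62.1 against 15.6% by the beta chain alone. Within CD8 T-like cells the expanded share was 45.4% with isotype, 71.9% with anti-PD-1 and 64.0% with anti-CTLA-4 in MOC1, 22.8, 52.5 and 67.2% in MOC1E1, and 56.4 and 82.1% in MOC22. With MOC22 cluster 0 counted as CD8, it was 26.1% (22.5 to 29.9%) with isotype and 81.99% with anti-PD-1. Clusters 4, 9 and 11, in which 88.0, 96.8 and 69.1% of cells held Cd8a, stayed outside this count. Their expanded shares were 74.7, 58.75 and 62.0% with isotype and 77.5, 74.1 and 71.2% with anti-PD-1. In MOC1 CD4 T-like cells the expanded share was 28.8, 26.7 and 45.9%, and in Treg-like cells 24.0, 13.3 and 3.70%. These shares depend on the number of cells in a class. An alternative chosen after seeing the data counted clones within a class alone and thinned treated and isotype cells to equal numbers. The shares above count clones over the whole library, so the values are not the same measure. By this alternative MOC1 Treg-like cells had 11.9 against 14.99% with anti-PD-1 and 0 against 4.38% with anti-CTLA-4. Over the draws the isotype values ran from 10.45 to 18.2% and from 0 to 14.8%, so no difference was detectable in these cells. CD8 T-like cells had 60.3 and 45.7 against 39.6% in MOC1, 34.3 and 41.5 against 19.6% in MOC1E1 and 62.95 against 52.3% in MOC22, the second MOC1 value with draws down to 39.6%. Their isotype cells were the fewer and were not thinned. Counted within the class before thinning, the treated values were 68.9 and 61.8% in MOC1, 49.2 and 65.7% in MOC1E1 and 80.0% in MOC22. The 10 largest clones held 4.64, 15.3 and 13.0% of MOC1 cells, 6.30, 14.96 and 21.7% of MOC1E1 cells, and 13.2 and 24.8% of MOC22 cells. The largest clone of MOC1 with anti-PD-1 had 177 cells (TRAV7N-4 with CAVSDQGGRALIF and TRBV1 with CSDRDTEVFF), of which 171 were CD8 T-like. All 169 of its cells with a tag carried hashtag 1, where the 10 largest clones held 34.6% of cells, against 13.5 to 23.2% in the other hashtags. With anti-CTLA-4 it had 74 cells (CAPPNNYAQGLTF and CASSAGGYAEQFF), and with isotype 24 cells that were all Treg-like (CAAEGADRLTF and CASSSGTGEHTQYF), where a cell with a second alpha chain counts as another clone. The largest MOC1E1 clones had 9, 49 and 23 cells, and the largest MOC22 clones 58 and 67. Merging clones with the same beta chain and a shared alpha chain, an alternative chosen after seeing the data, gave 35 cells for the largest MOC1 isotype clone, now one of mostly CD8 T-like cells (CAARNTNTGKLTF and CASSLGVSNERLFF). It gave 215 cells for MOC1 with anti-PD-1 and 118 for MOC22 with anti-PD-1.

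**Figure D2:**
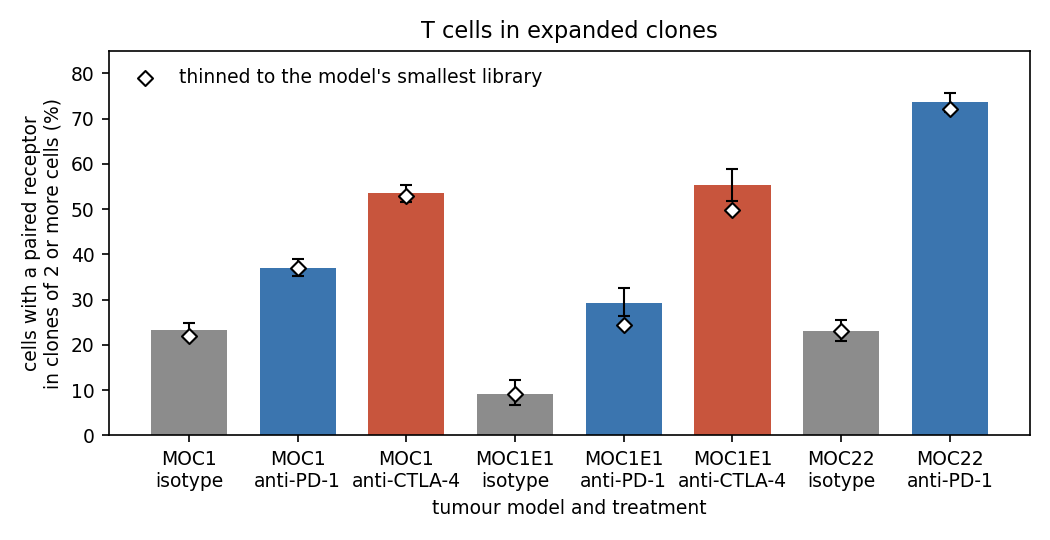
Bars give the share (%) of cells with paired receptor chains that belong to clones of 2 or more cells, by model and treatment, with exact 95% intervals, and diamonds give the share after thinning to equal cell numbers. The share is higher with each treatment than with isotype, up to 73.6% in MOC22 with anti-PD-1.

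Several of the largest clones carried alpha chains ending in the same residues, DYSNNRLTL, read from the TRAJ7 joining gene. The ending was chosen after the largest clones were seen, and the larger clones with it came from treated libraries. Their cells are counted in the shares below, so a higher share with treatment follows in part from the choice. The intervals below count cells of 1 clone as independent. In MOC1 1.06% of paired cells had it with isotype (33 cells), 7.40% with anti-PD-1 (200 cells) and 8.59% with anti-CTLA-4 (243 cells). In MOC1E1 the shares were 2.73, 18.75 and 32.0% (13, 168 and 240 cells), and in MOC22 1.89 and 22.4% (26 and 366 cells). Within CD8 T-like cells the ending made up 2.31% (1.00 to 4.51%), 15.4% (13.2 to 17.9%) and 12.7% (11.1 to 14.4%) in MOC1. It made up 5.435% (1.79 to 12.2%), 35.9% (30.9 to 41.1%) and 41.3% (37.0 to 45.7%) in MOC1E1, and 5.68% (3.22 to 9.20%) and 26.3% (23.8 to 28.9%) in MOC22, where adding cluster 0 gave 3.63% (2.26 to 5.49%) and 26.2%. The alpha chain CAASDYSNNRLTL together with the beta chain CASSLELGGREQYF occurred in 6 of 8 libraries and 124 cells, of which the isotype libraries of MOC1 and MOC1E1 held 1 cell each. The nucleotide version of the MOC1 isotype cell was also found in another library.

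**Figure D3:**
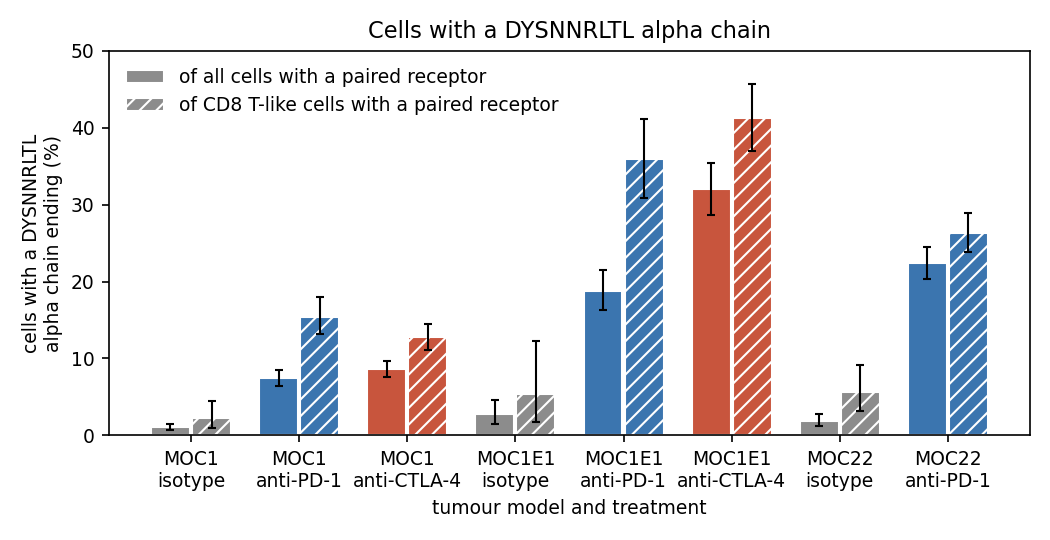
Solid bars give the share (%) of all paired cells, and hatched bars that of paired CD8 T-like cells, whose alpha chain ends in DYSNNRLTL, by model and treatment, with exact 95% intervals. Both are higher with treatment than with isotype, and highest in MOC1E1 with anti-CTLA-4 (32.0 and 41.3%). The ending was chosen from large clones of mostly treated libraries, whose cells are counted here.

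MOC1E1 tumours were set against MOC1 tumours without treatment, 3 libraries each. Krt13 (ENSMUSG00000044041, chromosome 11, 100117327 to 100121566 in GRCm38.p6), a keratin of the differentiating mucosa, fell from 213 ± 23.7 to 4.90 ± 2.52 TPM (SD, n = 3; log2 fold change -5.27, SE 0.297, limma, Benjamini-Hochberg adjusted p = 7.0e-05). Rhox5 (chromosome X, 37754608 to 37808878), a homeobox gene of the reproductive tract, rose from 14.8 ± 1.88 to 285 ± 25.9 TPM (log2 fold change 4.18, SE 0.115, limma adjusted p = 3.9e-06). Other large rises were Pip (1.16 to 22.1 TPM, log2 3.42), Mia (3.97 to 41.8 TPM), Scrg1 (1.81 to 22.1 TPM, log2 3.05) and Ndufa4l2, which hypoxia induces (41.0 to 203 TPM, log2 2.14, limma adjusted p = 0.0177). In limma 2820 of 15125 genes were called, 1014 up and 1806 down, and 5164 had an unadjusted p under 0.05. Quantile normalization gave 3603, of which 1957 were up, so the balance of directions depends on the scaling; a fit over all 12 libraries gave 5285, and 830 changed by at least 1 log2 unit. The count was 1530, 1273 and 1520 without MOC1 library 3, 4 or 5, and 1821 and 1639 without MOC1E1 library 1 or 2.

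Skeletal muscle genes fell the most: 14 of 15 tested were down (15 adjusted over the list alone), among them Acta1, the actin of skeletal muscle (373 ± 199 to 13.2 ± 11.2 TPM, log2 -5.20), the creatine kinase gene Ckm (167 to 5.52 TPM, log2 -5.02) and Ttn, the gene of titin (log2 -2.42). The list had a median of -3.83 (camera adjusted p = 8.5e-09, and adjusted p = 0.561 with an estimated correlation). Acta1 was 145.41 TPM in MOC1 library 3, against 460.74 and 513.85 in the other two, and 0.68 TPM in MOC1E1 library 3. Neutrophil markers fell in 8 of 10 (8 adjusted over the list alone), with S100a8 at 90.9 and 10.1 TPM (log2 -3.20), S100a9 at 98.1 and 12.5 TPM (log2 -3.00) and the receptor gene Csf3r (camera adjusted p = 1.1e-05, and adjusted p = 0.516 with an estimated correlation). Cytokines that attract myeloid cells fell in 7 of 13 (7 adjusted over the list alone): Ppbp from 278 ± 29.7 to 21.7 ± 2.86 TPM (log2 -3.62), Cxcl3 (log2 -4.02) and Cxcl5 (log2 -2.60) (camera adjusted p = 4.5e-05, and adjusted p = 0.516 with an estimated correlation). Macrophage markers fell in 8 of 18 (10 adjusted over the list alone), led by Arg1, the enzyme arginase 1, from 316 ± 10.1 to 37.6 ± 6.17 TPM (log2 -3.05), Cd14 (log2 -1.74) and Itgam (log2 -1.51) (camera adjusted p = 4.3e-06, and adjusted p = 0.541 with an estimated correlation). Cultured cells of both lines also hold Arg1 and Ppbp, lower in MOC1E1, and 5 of 7 macrophage list genes tested in cultures fell there. The tumour values thus do not separate cancer cells from macrophages. Among checkpoint ligands and suppressors 9 of 17 fell and 1 rose, with the same counts adjusted over the list alone: Nectin2, a ligand of receptors on T and NK cells, fell from 31.8 to 11.8 TPM (log2 -1.36) and Lgals9, the gene of galectin 9, rose from 81.3 to 178 TPM (log2 1.12) (camera adjusted p = 0.0179, and adjusted p = 0.611 with an estimated correlation). Cd274, the gene of the PD-1 ligand PD-L1, fell from 15.1 ± 0.499 to 5.30 ± 3.25 TPM (log2 -1.47, limma adjusted p = 0.0174), a call lost in 4 alternatives.

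In the same tumours 9 of 16 terminal differentiation genes of keratinocytes fell (9 adjusted over the list alone), with Krt13, the crosslinking enzyme gene Tgm1 (43.3 to 10.1 TPM, log2 -2.00) and Sprr3 (log2 -2.11) (camera adjusted p = 3.5e-06, and adjusted p = 0.516 with an estimated correlation). Of 16 epithelial adhesion genes 7 fell and 2 rose (7 and 3 adjusted over the list alone): the claudin gene Cldn3 fell from 139 to 41.9 TPM (log2 -1.71) and the epithelial factor Elf3 from 91.9 to 13.7 TPM (log2 -2.67) (camera adjusted p = 0.028, and adjusted p = 0.611 with an estimated correlation). Xenobiotic and aldehyde metabolism genes fell in 7 of 11 and rose in 1 (8 and 1 adjusted over the list alone), with the dehydrogenase genes Aldh3a1 (log2 -2.45) and Aldh1a3 (61.9 to 15.6 TPM, log2 -1.94) (camera adjusted p = 1.3e-04, and adjusted p = 0.516 with an estimated correlation). NRF2 targets fell in 6 of 15 and rose in 1 (8 and 2 adjusted over the list alone), among them Gsta4 (716 to 372 TPM) (camera adjusted p = 0.0267, and adjusted p = 0.617 with an estimated correlation). Hypoxia and glycolysis genes rose in 6 of 21 (6 adjusted over the list alone): the enolase gene Eno1 from 871 ± 26 to 1546 ± 254 TPM (log2 0.815), Hk1 (54.1 to 84.1 TPM) and Pfkl (62.1 to 101 TPM, a call lost in 4 alternatives) (camera adjusted p = 7.9e-04, and adjusted p = 0.653 with an estimated correlation). NF-kB targets fell in 5 of 17 (5 down and 1 up adjusted over the list alone), with Il1b at 25.6 and 6.79 TPM (log2 -1.75) (camera adjusted p = 0.0267, and adjusted p = 0.647 with an estimated correlation). Wnt targets fell in 2 of 11 (2 adjusted over the list alone), Rnf43 (log2 -1.75) and Wif1 (log2 -1.04), whose call was lost in 1 alternative (camera adjusted p = 0.0497, and adjusted p = 0.631 with an estimated correlation). Without 1 library the Wnt call was lost (adjusted p = 0.112, 0.126 and 0.115 without MOC1 library 4 or 5 or MOC1E1 library 3), as were those of epithelial adhesion (adjusted p = 0.0647 without MOC1 library 5) and NF-kB targets (adjusted p = 0.0694 without MOC1E1 library 1).

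Lists of other immune and stromal markers fell in these tumours as well. T cell attracting chemokines fell in 3 of 8 (3 adjusted over the list alone): Ccl21a (16.8 to 0.263 TPM, log2 -3.72), Cxcl12 (11.8 to 3.74 TPM) and Cxcl16 (107 to 72.0 TPM) (camera adjusted p = 0.0197, and adjusted p = 0.631 with an estimated correlation). Dendritic cell markers fell in 3 of 10 (4 adjusted over the list alone), Cd209a (log2 -1.01), Wdfy4 (log2 -1.06) and Itgax (log2 -0.54), calls lost in 1, 5 and 7 alternatives (camera adjusted p = 0.0267, and adjusted p = 0.631 with an estimated correlation). Regulatory T cell markers fell in 2 of 11 (4 adjusted over the list alone), Ikzf2 (log2 -0.81) and Lrrc32 (log2 -0.61), while Foxp3 itself stood at 2.10 and 1.16 TPM (limma adjusted p = 0.0691) (camera adjusted p = 0.0267, and adjusted p = 0.611 with an estimated correlation). Interferon gamma response genes fell in 2 of 24 (2 adjusted over the list alone), Cd274 and the complement inhibitor gene Serping1 (71.8 to 27.9 TPM) (camera adjusted p = 0.0413, and adjusted p = 0.836 with an estimated correlation). This call rests on single libraries: adjusted p = 4.9e-12 without MOC1E1 library 3, which held Ifit3, another interferon-induced gene, at 101.1 TPM against 19.38 and 17.54 TPM in the other two, but adjusted p = 0.313, 0.422 and 0.0549 without MOC1E1 library 1 or 2 or MOC1 library 5. Endothelial markers fell in 1 of 14 (0 adjusted over the list alone), Vwf, a call lost in 6 alternatives (camera adjusted p = 0.028, and adjusted p = 0.631 with an estimated correlation). Adipocyte markers fell in 1 of 8 (3 adjusted over the list alone), the lipase gene Lipe (log2 -1.05), lost in 3 alternatives (camera adjusted p = 0.0264, and adjusted p = 0.647 with an estimated correlation). Without a single library, some of these calls were lost. Dendritic, endothelial and T cell chemokine lists had adjusted p = 0.0786, 0.0787 and 0.0745 without MOC1 library 4 and adjusted p = 0.0666, 0.121 and 0.0666 without MOC1 library 5. Adipocyte markers had adjusted p = 0.0674 without MOC1 library 5. Without MOC1E1 library 2 endothelial, adipocyte and T cell chemokine lists had adjusted p = 0.124, 0.0949 and 0.0547, and without MOC1E1 library 3 dendritic and endothelial markers both had adjusted p = 0.0559. Camera thus called 18 of 30 lists, none of them with an estimated correlation. It called 11 without MOC1 library 5, and 19 without MOC1E1 library 3, of which 15 were among the 18. Mitochondrial transcripts took 4.87 to 5.90% of TPM in MOC1 tumours and 6.92 to 8.05% in MOC1E1 tumours.

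The other 12 lists were not called in tumours, but several of these non-calls rest on MOC1E1 library 3, where Ifit3 stood at 101.1 TPM against 19.38 and 17.54 TPM in the other two. Without that library camera called type I interferon (adjusted p = 5.6e-07), MHC class I (adjusted p = 0.0016), T cell (adjusted p = 0.0012) and CD8 cytotoxic genes (adjusted p = 6.9e-04), all downward. Fibroblast markers were called downward without MOC1 library 3 (adjusted p = 0.0125) or MOC1E1 library 1 or 2 (adjusted p = 0.0196 and adjusted p = 0.0194). MHC class I genes had 0 of 19 called, MHC class II 1 of 11 (down), type I interferon 1 of 30 (down), T cell markers 2 of 15 (down), CD8 cytotoxic markers 0 of 10 and fibroblast markers 2 of 19 (down), with medians of -0.05, -0.09, -0.16, -0.37, -0.49 and -0.46. Adjusted over the list alone the counts were 0, 0, 0, 1, 0 and 2. Basal keratinocyte genes had 3 up and 4 down of 17 (7 and 4 adjusted over the list alone), with Krt6a at 2779 and 1108 TPM (log2 -1.33), and their median of 0.08 and mean of -0.10 differ in sign. Mesenchymal genes had 2 up of 15 (2 up and 1 down adjusted over the list alone), including Vim (log2 0.81), with a median of -0.03, a mean of 0.01 and a median of 0.04 after quantile normalization. Cell cycle genes had 1 down of 27 (1 adjusted over the list alone), with a median of -0.04 against an upward test and a median of 0.01 after quantile normalization. Oxidative phosphorylation had 5 down of 23 (5 adjusted over the list alone), including Ndufa4 (973 to 521 TPM, log2 -0.90), with a median of -0.08; after quantile normalization 2 were up and 2 down, with a median of -0.03. ERK pathway targets had 2 up and 4 down of 17 (2 and 4 adjusted over the list alone), with a median of 0.10 and a mean of -0.08. Targets of p53 had 3 up and 5 down of 15 (3 and 5 adjusted over the list alone), including Cdkn1a, the cell cycle inhibitor p21 (78.4 to 42.0 TPM), with a median of -0.21.

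Cultured MOC1E1 cells were set against cultured MOC1 cells, 3 libraries each, to compare the lines without a host. The columns of this table carry an interferon gamma mark in their names, while the labels give no treatment. Interferon-induced genes were far lower in MOC1E1 cells: Ifit3, an antiviral gene, fell from 110.1 ± 6.24 to 3.04 ± 0.265 TPM (SD, n = 3; log2 fold change -4.78, limma adjusted p = 5.9e-08). Cxcl9, a chemokine gene that interferon gamma induces, fell from 149 ± 4.08 to 9.89 ± 0.309 TPM (log2 -3.78, limma adjusted p = 4.5e-08), and Cxcl10 from 274 to 35.5 TPM (log2 -2.91). Type I interferon response genes fell in 29 of 30, interferon gamma response genes in 23 of 24, with Socs3 rising (log2 0.46), and MHC class II genes in 8 of 8, with H2-Aa at 198 and 47.4 TPM (log2 -2.04). The same members passed in number when adjusted over the list alone, and camera gave adjusted p = 3.1e-14, 9.9e-10 and 2.5e-06. With an estimated correlation the 3 lists had adjusted p = 0.0681, adjusted p = 0.0983 and adjusted p = 0.0681. MHC class I genes fell in 13 of 19 and rose in 3 (13 and 3 adjusted over the list alone), among them Tapbp (log2 -0.76) and H2-T23 (264 to 110 TPM, log2 -1.26) (camera adjusted p = 0.0319, and adjusted p = 0.272 with an estimated correlation). Myeloid attracting cytokines fell in 11 of 11 (11 adjusted over the list alone), with Il1a (70.8 to 4.39 TPM, log2 -3.74) and Ppbp (1123 to 192.5 TPM, log2 -2.54) (camera adjusted p = 8.0e-07, and adjusted p = 0.0983 with an estimated correlation). Checkpoint ligands and suppressors fell in 14 of 15 (14 down and 1 up adjusted over the list alone), with Cd274 (log2 -1.88), Nectin2 (67.4 to 19.4 TPM, log2 -1.74) and Cd80 (7.36 to 0.663 TPM) (camera adjusted p = 3.2e-06, and adjusted p = 0.0755 with an estimated correlation). NF-kB targets fell in 12 of 14 (12 down and 1 up adjusted over the list alone), with Tnfaip3 (log2 -1.58) (camera adjusted p = 8.5e-04, and adjusted p = 0.272 with an estimated correlation).

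Other genes separated the cultured lines as well. Rhox5 rose from 28.1 ± 2.02 to 842 ± 28.8 TPM (log2 4.86, SE 0.060, limma adjusted p = 4.5e-08), Igfbp2, an insulin-like growth factor binding protein, from 11.1 to 94.1 TPM (log2 2.98) and Vim, the gene of vimentin, from 516 to 1612 TPM (log2 1.64). Stra6, a retinol receptor, fell from 67.7 to 0.670 TPM (log2 -5.36), Lcn2, an antibacterial lipocalin, from 95.1 to 2.30 TPM (log2 -4.89) and Nos2, the inducible nitric oxide synthase, from 83.5 to 2.74 TPM (log2 -4.50). Cell cycle genes rose in 15 of 27 and fell in 2 (15 and 3 adjusted over the list alone), with Mcm5 at 146 and 213 TPM (camera adjusted p = 2.1e-04, and adjusted p = 0.174 with an estimated correlation). Oxidative phosphorylation genes rose in 7 and fell in 3 of 24 identifiers, with Ndufa4 at 512 and 907 TPM (camera adjusted p = 0.0254, adjusted p = 0.0595 without MOC1 library 5, and adjusted p = 0.273 with an estimated correlation). Fibroblast markers fell in 5 of 6 and rose in 1 (5 and 1 adjusted over the list alone), with Sparc, a matrix protein, at 89.6 and 3.51 TPM (camera adjusted p = 0.0254, and adjusted p = 0.198 with an estimated correlation). Macrophage list genes that the cells express fell in 5 of 7 (5 adjusted over the list alone), with Arg1 at 134 and 39.4 TPM (camera adjusted p = 0.021, and adjusted p = 0.267 with an estimated correlation). In limma 7461 of 13975 genes were called, 2821 up and 4640 down. Quantile normalization gave 7832, of which 4285 were up, and moved the median of all genes from -0.06 to 0.06; 1059 genes changed by at least 1 log2 unit. Camera called 11 of 21 lists, none of them with an estimated correlation.

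The other 10 lists were not called in cultures. Epithelial adhesion genes rose in 7 and fell in 7 of 16 (8 and 7 adjusted over the list alone), with Elf3 at 112 and 28.7 TPM and a median of 0.08 against a mean of -0.17. Basal keratinocyte genes rose in 4 and fell in 7 of 17, terminal differentiation genes rose in 3 and fell in 5 of 10, and mesenchymal genes rose in 2 and fell in 8 of 13, with medians of -0.05, -0.29 and -0.46. Mesenchymal genes were called downward without MOC1 library 5 or 6 (adjusted p = 0.0280 and adjusted p = 0.0355). Hypoxia and glycolysis genes rose in 6 and fell in 8 of 20, ERK pathway targets rose in 8 and fell in 6 of 16, and NRF2 targets rose in 7 and fell in 4 of 14, with medians of -0.15, 0.16 and 0.19. Xenobiotic metabolism genes rose in 2 and fell in 6 of 10, p53 targets rose in 3 and fell in 6 of 13, and Wnt targets rose in 2 and fell in 2 of 7, with medians of -0.64, -0.14 and -0.10. The medians of basal keratinocyte, p53 and Wnt genes changed sign after quantile normalization.

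**Figure D4:**
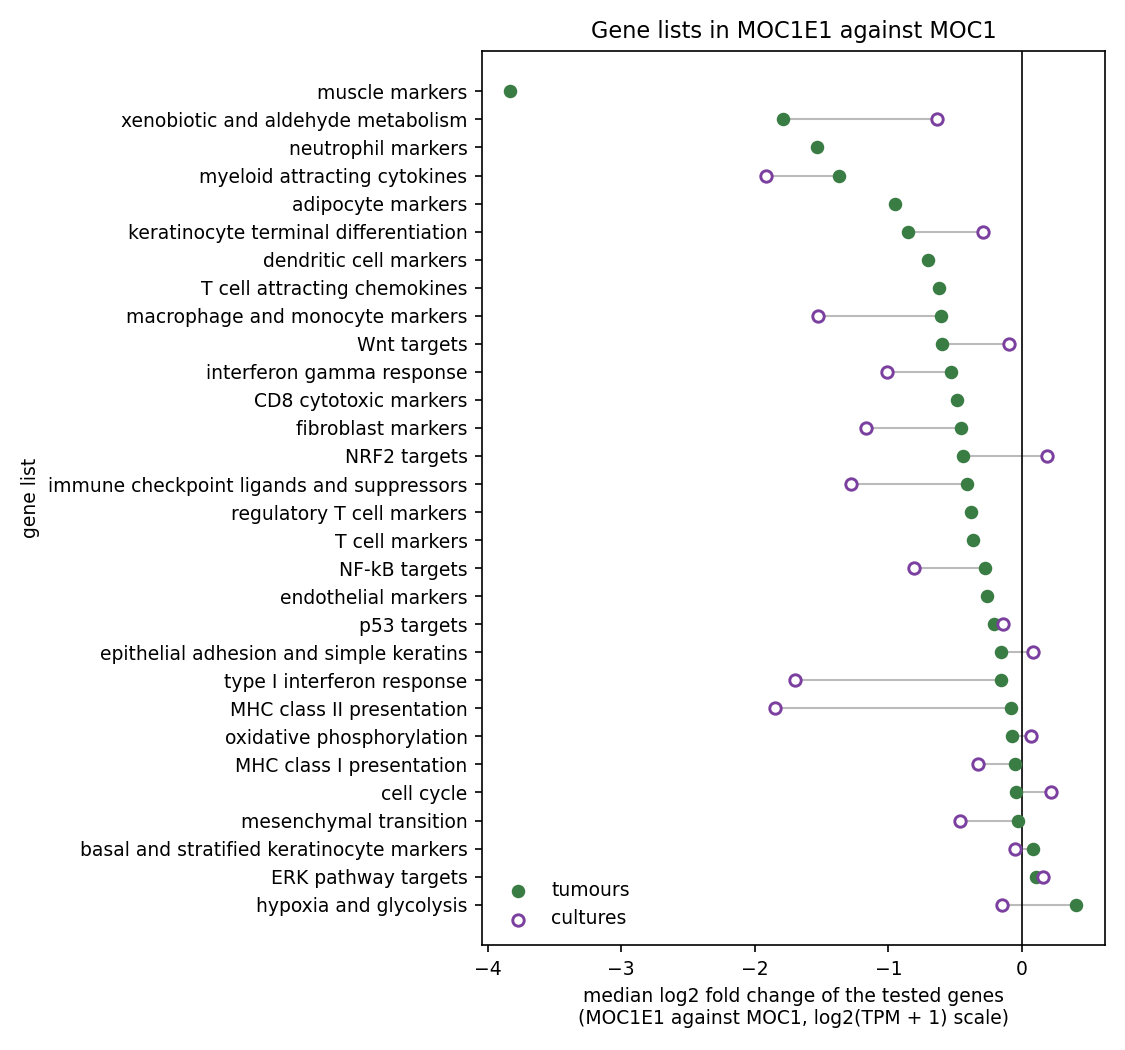
Each point is the median log2 fold change (log2(TPM + 1) scale, MOC1E1 against MOC1) of the tested genes of a list, filled for tumours and open for cultures, with a line joining both. Muscle markers lie lowest in tumours (-3.83), and MHC class II genes lie at -1.85 in cultures and -0.09 in tumours, whose RNA includes that of host cells.

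The interaction asked whether MOC1E1 and MOC1 differ in another way in tumours than in culture. Among the 8 genes with the smallest p were Cd74 and H2-Eb1, which serve MHC class II presentation: Cd74 stood at 565 and 148 TPM in cultured MOC1 and MOC1E1 cells and at 1110 and 1060 TPM in tumours (interaction log2 1.86, SE 0.088, limma adjusted p = 3.2e-07), and H2-Eb1 at 212 and 54.05 TPM in culture and 504 and 474 TPM in tumours (interaction log2 1.87). The MHC class II list as a whole was not tested for an interaction. Tumour libraries hold RNA of host cells too. In the MOC1E1 single-cell libraries, H2-Ab1, H2-Aa and H2-Eb1 were among the leading genes of a macrophage-like cluster. The tumour values therefore do not show the level in cancer cells. Culture columns carry the interferon gamma mark in their names. Krt79 rose in culture (11.9 to 81.0 TPM) and fell in tumours (454 to 284 TPM), an interaction of -3.35. Psca, a surface antigen, fell in tumours from 519 to 30.04 TPM and stood at 13.0 and 16.7 TPM in culture (interaction -4.39). Trpv6, a calcium channel gene, fell in culture (20.8 to 2.65 TPM) and rose in tumours (9.05 to 18.4 TPM; interaction 3.54). Stra6 fell more in culture than in tumours, where it stood at 224 and 86.8 TPM (interaction 3.98), as did Tmem176a (interaction 2.48); Ak3 had an interaction of 1.84. Limma called 2828 of 16813 genes, 1717 with a positive and 1111 with a negative interaction. Quantile normalization gave 3074, of which 1714 were positive, and 1102 had an absolute interaction of at least 1.

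Many genes differed between the lines the same way in both settings. Of 12378 genes tested in both, 607 rose in both (198.0 by chance, Fisher's exact p = 2.2e-202), Rhox5 among them, and 1038 fell in both (456.6 by chance, Fisher's exact p = 4.1e-274). In opposite directions 126 were called. Log2 fold changes correlated at Pearson's r = 0.535 and Spearman's rho = 0.546 across genes, which are not independent replicates.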

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

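The tests that weigh explanations for the muscle genes and the counts over splits of the libraries were chosen only after the results were seen, while the interaction between line and setting was planned. The MOC1E1 effect differed between tumours and cultures for 8 genes named by the smallest p (tumour minus culture log2 difference, limma): Krt79 at -3.35, Psca at -4.39, Trpv6 at 3.54, H2-Eb1 at 1.87, Ak3 at 1.84, Tmem176a at 2.48, Stra6 at 3.98 and Cd74 at 1.86. With 100 splits drawn for the interaction, 2 gave as many genes, the real split included. The real count was 2828 and the highest other was 3120, from a split that kept the cultured lines apart and mixed the tumours. Calls can thus arise from the culture difference alone, and the splits do not exclude chance for the difference between tumours and cultures. For the tumour and the culture comparisons the 6 libraries make 10 splits, too few for a share under 0.05. The real split called 2820 genes in tumours and the highest other 0, and 7461 genes in cultures and the highest other 1.

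Clones also showed a signal in the hashtags of the MOC1 libraries. With anti-CTLA-4, hashtags 1 and 2 shared 91 clones, and cells of these clones made up 42.6% and 48.2% of the cells with these tags. Hashtags 3 and 4 shared 22 clones there, and any pair with isotype or anti-PD-1 shared 0 to 3. Clones of 2 or more cells lay in a single hashtag in 212 of 215 cases with isotype, 191 of 196 with anti-PD-1 and 179 of 294 with anti-CTLA-4, against at most 65, 45 and 60 with the tags shuffled.

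Muscle genes were the lowest list in MOC1E1 tumours, with a median log2 fold change of -3.83. A lower share of cancer cells in MOC1 tumour pieces would move markers of other host cells by about as much, which the endothelial median of -0.26 argues against. Medians of the other immune and stromal marker lists were also negative, from -0.37 for T cell to -1.53 for neutrophil markers. A smaller difference in the share of host cells therefore stays open. Skeletal muscle tissue in the MOC1 pieces may account for the fall: 13 of 15 muscle genes had a mean TPM in MOC1 cultures more than 10 times below that in MOC1 tumours, with Acta1 at 373 TPM in tumours and 0.38 TPM in culture. Tnni2 and Mb were exceptions, at 24.1 and 7.20 TPM in MOC1 cultures. Whether the amount of muscle follows the line, the site of growth or the dissection stays open.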

How the results depend on the processing

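Alternatives of the doublet rule by hashtag and by cell number, the merging of clones over alpha chains and the thinning of clones within classes were chosen after seeing the data; the others were planned. Of 2098 values of named bulk genes under alternatives, 1971 kept direction and side of the threshold, 112 lost and 15 gained a call, and 0 reversed. Of 740 values of named genes in cells, 318 stayed within their interval, 418 moved and 4 reversed; the cause was not tested for those below. H2-Aa in Treg-like cells with anti-CTLA-4 had a log2 ratio of 1.33 in MOC1 and -1.75 with classes read from transcripts, and 1.58 in MOC1E1 and -2.44 with transcripts and -0.18 with doublets kept. H2afx in MOC1E1 Treg-like cells with anti-CTLA-4 went from -2.17 to 0.16 with transcripts. Genes called in tumours (2820) fell to 830 with an absolute log2 change of at least 1, by the alternative's construction, and were 5285 in a fit of all 12 libraries; leaving out each library in turn gave 1273 to 2645. Cultures (7461) gave 1059 at that limit and 6168 to 6653 leaving out each library, and the interaction (2828) gave 1102 and 2011 to 3012. Lists called by camera in tumours (18) and cultures (11) were 0 and 0 with an estimated correlation, 10 and 18 by fry with a direction, and 21 (16 of them among the 18) and 21 by fry in either direction; leaving out each library gave 11 to 19 and 11 to 12. Of the 19 without MOC1E1 library 3, 15 were among the 18, and type I interferon, MHC class I, T cell and CD8 cytotoxic genes were added. No value exists for 48 pairs of gene and left-out library, because the gene no longer passed the filter. Alternatives for counts (other normalizations and dispersion models) were not run, since the tables hold TPM. No paired analysis was possible because the bulk columns carry no numbers that pair the lines. TPM hides depth, so limits of the bulk values cannot be given, and counts of 55 to 102 Treg-like cells limit the anti-CTLA-4 libraries.

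Share differences in percentage points moved as follows, and the cause was not tested. By transcripts, CD8 differences were 21.8 for MOC1 with anti-PD-1 (19.8 by cluster), 41.2 with anti-CTLA-4 (45.3), 10.8 and 38.8 for MOC1E1 (17.2 and 48.4) and 28.0 for MOC22 (57.0); Treg-like differences were -16.3, -31.6, -16.6 for MOC1E1 with anti-CTLA-4 and -2.62 for MOC22. Thinned to 2000 UMIs, CD8 differences were 22.95, 42.7, 12.4, 39.97 and 28.8, and Treg-like differences -11.7, -22.8, -11.6 and -1.53 in the same order. Under the stricter filter, CD8 differences were 47.3 for MOC1 with anti-CTLA-4 and 30.6 for MOC22, and Treg-like differences -20.99, -39.9, -18.1 and -1.80. With doublets kept, CD8 differences were 50.4 for MOC1 with anti-CTLA-4 and 28.4 for MOC22, and Treg-like differences -39.2 and -1.42. Removing hashtag doublets as well gave -39.0 for MOC1 Treg-like cells with anti-CTLA-4. At resolution 0.5 MOC22 gave 26.2 for CD8 and -1.56 for Treg-like cells, and at resolution 2 it gave -1.60 for the latter. The effector list of MOC1 with anti-CTLA-4 gave 0.41 by transcripts (0.06), the memory list of MOC1E1 with anti-PD-1 -0.52 (-0.12), and the stricter filter gave 0.082 and -0.175 for the effector and memory lists of MOC22.

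Differences in the share of expanded cells moved too. By the beta chain alone they were 12.8 and 33.6 for MOC1, 46.5 for MOC1E1 with anti-CTLA-4 and 53.96 for MOC22, against 15.2, 31.1, 40.5 and 49.0. With clones of at least 3 cells they were 34.1 for MOC1E1 with anti-CTLA-4 and 44.6 for MOC22. With at least 5 cells they were 26.2 for MOC1 with anti-CTLA-4, 10.3 and 25.9 for MOC1E1 and 38.4 for MOC22. Without thinning they were 20.1 and 46.1 for MOC1E1, and by the clonotype numbers as deposited 9.66 for MOC1E1 with anti-PD-1. Merging clones over alpha chains left all 5 differences within their intervals (14.4 to 50.6).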

Other observations

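CD4 T-like cells, the helper T cell class, had more T helper 1 transcripts with each treatment in MOC1 and MOC1E1; in MOC22, 67 and 19 such cells gave no list values. In MOC1 with anti-PD-1, 20 of 22 effector genes and 11 of 12 T helper 1 genes were higher (median log2 ratios 0.68 and 0.58), as were 12 of 18 dissociation and stress genes (median 0.19), with Ifng 4.63 times as high (4.08 to 5.27) and Lag3 at 481 against 180.0 CPM. With anti-CTLA-4, 11 of 12 T helper 1 genes were higher (median 0.60), 14 of 23 effector genes higher and 9 lower (median 0.12) and 25 of 26 type I interferon genes lower (median -0.64), with Cxcr6 at 543 against 228 CPM, Tigit at 548 against 234 CPM and Klf2 at 64.7 against 450 CPM. In MOC1E1 with anti-PD-1, 21 of 21 effector genes (median 0.82) and 11 of 11 T helper 1 genes (median 0.63) were higher, with Ccl5 at 1905 against 699 CPM and Gzmk at 50.9 against 5.0 CPM. With anti-CTLA-4 there, T helper 1 genes had a median of 1.01 (9 of 12 higher), effector genes 0.725 (17 of 22 higher), dissociation and stress genes 0.37 (12 of 17 higher), glycolysis genes 0.84 (13 of 13 higher) and memory genes -1.12 (15 of 18 lower), with Klf2 at 109 against 814 CPM and Ctla4 at 216 against 73.6 CPM. RNA from CD8 T cells was not separated: with anti-PD-1, Cd8b1 stood at 161 against 69.4 CPM in these cells of MOC1 and at 61.4 against 84.7 CPM in MOC1E1; with anti-CTLA-4 it stood at 73.4 and 68.9 CPM. MOC1 CD4 T-like cells came mostly from cluster 3 with isotype (539, with 168 in cluster 2) and anti-PD-1 (413, with 246 in cluster 2) and from cluster 2 with anti-CTLA-4 (762, with 93 in cluster 3).

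The tests of both hypotheses that follow were chosen only after the results were seen. The DYSNNRLTL receptor ending was more frequent in each treated library, in part because it was chosen from large clones of mostly treated libraries. Cells or transcripts carried over between libraries would share nucleotide sequences, but of 10 nucleotide versions of the receptor shared by 6 libraries 1 was found in more than 1 library. The share within CD8 T-like cells was above isotype in 5 of 5 contrasts. This share counts the cells of the large clones from which the ending was chosen, and most of those are CD8 T-like. It cannot decide whether more CD8 T-like cells account for the higher frequency. The intervals of this share count cells of 1 clone as independent, and each contrast has 1 library per group. They therefore do not measure the spread between mice. Among receptors seen in 1 cell the share with the ending was higher in all 5 contrasts, with an interval above that of isotype in 4 of 5. The intervals overlap for MOC1E1 with anti-PD-1 (4.74 against 1.85%). This cannot decide whether a few clones grew. A cell of a grown clone with a second alpha chain counts as another receptor, and the share was not recomputed on merged clones. Selection of many separate T cell clones by a shared antigen may be involved, which no antigen test in these data addresses.

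In MOC22, cluster 9 (219 cells) held Foxp3 in 96.8% and Cd8a in 96.8% of its cells, and made up 4.46% of cells with isotype and 3.64% with anti-PD-1. Doublets of a CD8 and a regulatory T cell would carry Cd4, which 4.11% of its cells held against 61.0% of Treg-like cells; more than 1 beta chain, another sign of doublets, was found in 6.86% of them against 2.45% of CD8 T-like and 4.06% of Treg-like cells, so some doublets among them stay open. Free Foxp3 RNA would reach other CD8 T cells alike, yet 2.25% of CD8 T-like cells held Foxp3, at median depths of 6249 UMIs in cluster 9 and 5980 in CD8 T-like cells. That share ran from 0.529% in cluster 6 to 14.3% in cluster 10. It was 9.64 and 15.4% in clusters 4 and 11, which are rich in Cd8a but outside the class. Foxp3 is a leading gene of cluster 9, so its own share is set in part by the clustering. Of the cluster 9 cells with paired receptors 90 of 138 were expanded (65.2%), against 8 of 170 Treg-like cells (4.71%). In cluster 9, 80 cells shared clones with CD8 T-like clusters and 4 (2.90%) with Treg-like cells. Sharing with Treg-like cells was as rare among CD8 T-like cells (41 of 1466, 2.80%). These counts of shared clones therefore do not decide between doublets and CD8 T cells that express Foxp3. The latter remain a candidate explanation, found and tested on the same cells.

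In the isotype MOC1 library an unnamed cluster 17 held 69 cells, and 0 cells with anti-PD-1 or anti-CTLA-4, each of which allows a share of up to 0.084% (3 counts). The MOC1 anti-CTLA-4 library held a clone of 31 cells (TRAV7-4 with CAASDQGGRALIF and TRBV1 with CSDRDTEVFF) whose beta chain has the amino acids of the largest clone with anti-PD-1. Bulk libraries correlated at 0.971 to 0.983 within a line and 0.938 to 0.955 between lines in tumours, and at 0.988 to 0.992 and 0.947 to 0.956 in cultures, across genes, which are not independent replicates.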
